A study of Mus musculus with 12 samples.

How the data were processed

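Small-RNA libraries were made from the hippocampi of 6 WT and 6 GLD2KO mice. Per the labels' protocols, total RNA was extracted with TRIzol, a size fraction was cut from a gel, and barcoded cDNA libraries were sequenced on an Illumina HiSeq instrument. The sources state the size fraction in 2 ways that differ in their lower bound, so the exact range is left open here. The submitters' processing notes name Trimmomatic 0.32, cutadapt 1.3 and the genome build GRCm38. The aligner, the counting tool, the miRNA annotation and the treatment of reads that match several miRNAs are not given in the sources used here. In 6 groups, 14 of the tested miRNAs have the same counts in all 12 libraries, as when shared reads are given to each name in full or in equal parts. All of these have miR-297, miR-466, miR-467 or miR-669 names, and none is a let-7. As the treatment of shared reads is unknown, other near-identical miRNAs, such as members of the let-7 family, are also uncertain as single values. The deposited table holds whole-number counts per mature miRNA and library, without normalization by the authors. Size selection, trimming and ligation set which RNAs enter such counts, so they compare one miRNA between libraries better than different miRNAs within a library. No molecular identifiers are named, and intervals on counts of a single library cover counting error only.

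Groups and replicate numbers were taken from the sample titles, and the table's columns were matched to samples by name. The labels describe separate mice, and no batch or day is given. The table had 1908 rows that name a miRNA and 1 row that names none, which held 0 counts and was left out of library sizes and tests. Hairpin positions came from an annotation of the same build, GRCm38, in which 1892 of the 1908 names matched a hairpin gene. A hairpin's host gene is one that contains it on the same strand.

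Counts were tested in R 4.3.3 with edgeR 4.0.16 (TMM factors, glmQLFit, glmQLFTest, filterByExpr by genotype), which left 521 miRNAs with 99.96% of all counts. Log2 fold changes are GLD2KO minus WT with 95% confidence intervals from the same model. CPM values used the TMM-scaled library sizes, and log2 CPM used a prior count of 2. P values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Lists of miRNAs were tested with camera from limma 3.58.1 at a preset correlation of 0.01, where at least 3 members were tested, and with fry and an estimated correlation beside it. Camera compares a list with the other miRNAs, and fry asks whether its members move one way. Arm ratios, as log2 of 5p over 3p counts with a pseudocount of 0.5, were tested with limma for hairpins with a mean of at least 10 counts in both arms. Shares, library measures and the let-7 group difference were compared by two-sided exact permutation over all 924 relabellings.

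The tests, the 17 lists and the rule for named miRNAs were fixed before the data were examined. The lists were the let-7 family and its groups II and I, neuron-enriched, activity-regulated, oligodendrocyte, microglia and blood, vascular, choroid plexus and cilia, other brain regions, Dlk1-Dio3, Sfmbt2, miR-17-92, miR-30, miR-29, injury and hypoxia, and miRNAs reported for Gld2. They were written from textbook knowledge and share some members. The rule named the 10 most abundant miRNAs, the 10 with the lowest p, the 2 most abundant members and the member with the lowest p of each list, and miR-122-5p and miR-134-5p. Other miRNAs are said to be named after their values were seen, or stand in a count of all calls or list members.

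The tests were checked on simulated counts for the same 521 miRNAs and 12 libraries, with 200 miRNAs changed, over 5 rounds. The edgeR test recovered 28.1% of 2-fold, 90.9% of 4-fold and 100% of 8-fold changes, and 2.93% of its calls were unchanged miRNAs. The 95% intervals held the true value for 95.7%. With 20 miRNAs changed, 73% of 4-fold changes were recovered. With no change simulated, 0 miRNAs were called in 10 rounds. For 20 hairpins with an 8-fold arm change, 85% were recovered. Each miRNA was drawn independently at its fitted spread, without the shared deviations and far single libraries seen in the real data. These rates may therefore be better than those that hold here, and random splits of the real libraries gave up to 2 calls.

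Alternatives were DESeq2 1.42, limma-voom with and without quality weights, other scalings and filters, a robust fit, a surrogate variable (sva 3.50), the replicate number as a block, other pseudocounts and minimums, and leaving out each library in turn. Leaving out 3 outlying libraries and counting miRNAs with the same counts once were added after seeing the data. A value was counted as reversed only where its sign changed and either value passed the threshold, or the move exceeded its error (the SE, or the SD over members for a list). This definition was narrowed after a plain change of sign had marked many values near 0, and all sign changes are counted beside it. Random splits, correlations between miRNAs and figures used R and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Individual reads, and with them untemplated nucleotides, were not analysed here.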

Results

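Small RNAs of the hippocampus were sequenced from 12 male C57BL/6 mice aged 3 months. The mice were littermates, 6 of them wild type (WT) and 6 carrying a knockout of Gld2 (GLD2KO). Gld2, also named Tent2 (GRCm38, chromosome 13, 93145855 to 93192435), encodes a poly(A) polymerase that adds adenosines to the 3′ ends of RNAs, miRNAs among them. The study addresses the part this enzyme plays in adding untemplated nucleotides to miRNAs. The deposited table gives counts per miRNA, so the comparison made here is of miRNA counts between the genotypes, as a measure of relative abundance. Counts were scaled to each library, so a rise or fall shared by all miRNAs could not be seen. Whether changed 3′ ends alter how a miRNA is ligated or counted could not be examined. Added nucleotides and the Gld2 mRNA were not analysed here, and the genotypes are as labelled.

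The table listed 1908 miRNAs, of which 1325 had at least 1 count. Libraries held between 2197915 and 3761106 counts, with means, in units of 1000000 counts, of 3.10 ± 0.509 in WT and 2.49 ± 0.213 in GLD2KO (SD, n = 6 each). The difference of -0.614 had a two-sided exact permutation p of 0.0238, and an adjusted p of 0.0714 over the 3 library measures compared. Without GLD2KO replicate 5 the difference was -0.557 and the unadjusted exact p was 0.0519. WT libraries held 876 ± 63.8 miRNAs with at least 1 count and GLD2KO libraries 866 ± 43.7 (exact permutation, adjusted p = 0.76). The 10 most abundant miRNAs of each library took 60.1 ± 4.59% of counts in WT and 57.4 ± 3.79% in GLD2KO (exact permutation, adjusted p = 0.442). Correlations of log2 counts per 1000000 (CPM) between libraries ran from 0.878 to 0.970 across miRNAs, with a median of 0.937 within a genotype and 0.934 between genotypes; miRNAs are not independent replicates.

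The most abundant miRNAs of these hippocampi were let-7c-5p and miR-124-3p, and neither passed the test of a genotype difference. The level of let-7c-5p was 153395 ± 54461 CPM in WT and 126154 ± 49354 CPM in GLD2KO (SD, n = 6 each). It is encoded by Mirlet7c-1 (GRCm38, chromosome 16, 77599657 to 77599750, in an intron of Mir99ahg) and Mirlet7c-2 (chromosome 15, 85706603 to 85706697, in an exon of Lncppara). The neuronal miR-124-3p, with 3 hairpins on chromosomes 2, 3 and 14, was at 130905 ± 76640 CPM in WT and 98413 ± 21711 CPM in GLD2KO. The neural miR-9-5p was at 52072 ± 21025 and 62499 ± 41195 CPM. Levels of miR-29b-3p, a member of a family that rises as neurons mature, were 66968 ± 18270 and 46990 ± 18959 CPM. Over the 10 most abundant miRNAs the log2 fold change, GLD2KO minus WT, lay between -0.51 (miR-29b-3p, SE 0.37) and 0.26 (miR-9-5p, SE 0.46).

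Among all 521 miRNAs with enough counts to test, 0 passed a Benjamini-Hochberg adjusted p of 0.05 in edgeR's quasi-likelihood test, and the lowest adjusted p was 0.815. An unadjusted p under 0.05 was reached by 25 miRNAs, 17 higher and 8 lower in GLD2KO, where chance gives 26.05 on average. DESeq2 called 0 of 1317 miRNAs, with 45 at an unadjusted p under 0.05, and limma-voom called 0, with 23. With no low-count filter, edgeR called 7 of 1325 miRNAs, miR-103-1-5p, miR-1298-5p, miR-1912-5p, miR-20b-5p, miR-22-3p, miR-331-3p and miR-539-5p. Of these miR-103-1-5p had 226 counts in WT replicate 5 and 1 to 12 in each other library, and miR-1912-5p, from an intron of Htr2c, 66 in GLD2KO replicate 6 and 0 to 3 in each other library. Over the tested miRNAs 306 were higher and 215 lower in GLD2KO, with a median log2 fold change of 0.12.

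**Figure D1:**
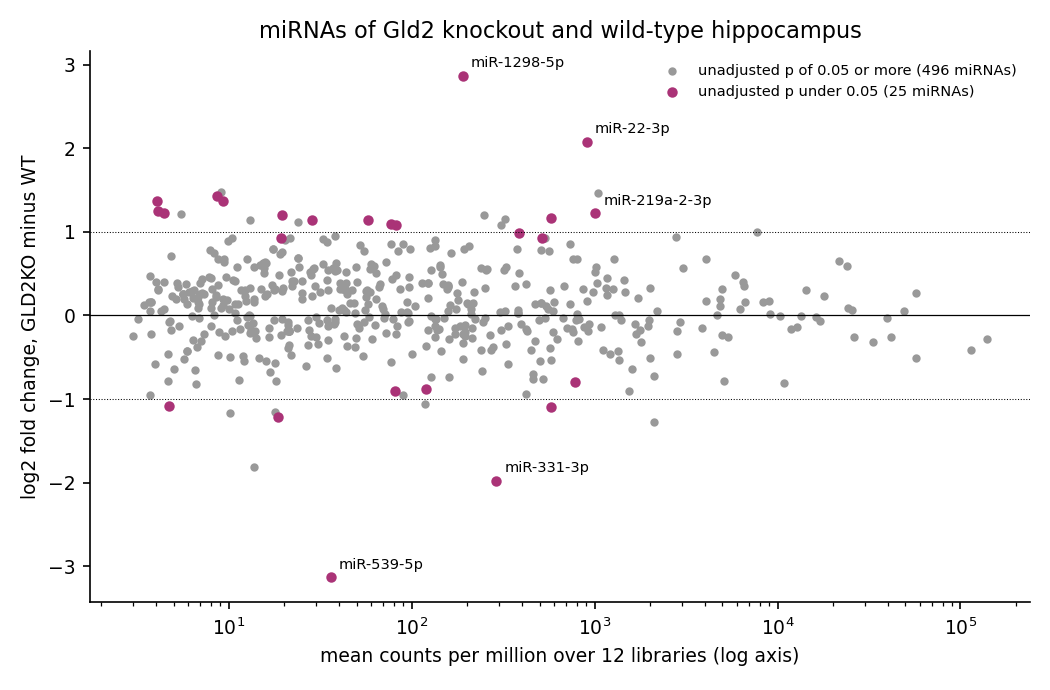
Log2 fold change (GLD2KO minus WT) of the 521 tested miRNAs against their mean CPM over the 12 libraries, on a log axis, with dotted lines at a 2-fold change. Of these, 25 miRNAs with an unadjusted p under 0.05 are coloured, 0 passed the adjusted threshold, and the 10 most abundant miRNAs lie between -0.51 and 0.26.

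Of the 10 miRNAs with the lowest p, the most abundant was miR-219a-2-3p, an oligodendrocyte miRNA that takes part in myelination (GRCm38, chromosome 2, 29845631 to 29845727, within no other gene on its strand). Its level was 604 ± 310 CPM in WT and 1410 ± 368 CPM in GLD2KO, a log2 fold change of 1.22 (SE 0.41, edgeR adjusted p = 0.815), and all 6 GLD2KO libraries lay above all 6 WT libraries. A pair of large fold changes each rested on 1 library. The imprinted miR-539-5p (chromosome 12, 109728129 to 109728202) had a log2 fold change of -3.13 (SE 0.97), with 334 CPM in WT replicate 5, and -0.60 without that library. For miR-1298-5p, encoded in an intron of the serotonin receptor gene Htr2c (chromosome X, 147064905 to 147065002), it was 2.87 (SE 0.95), with 1767 CPM in GLD2KO replicate 6, and 0.04 without that library. For miR-22-3p (chromosome 11, 75463716 to 75463810, in an exon of Mir22hg) it was 2.08 (SE 0.73), and 0.75 without GLD2KO replicate 1. The level of miR-331-3p, from an exon of Vezt, was 463 ± 409 CPM in WT and 118 ± 119 CPM in GLD2KO, a log2 fold change of -1.97 (SE 0.72). Without each library in turn that fold change ran from -2.71 to -1.54. The others were miR-149-5p at 1.16 (SE 0.44), miR-133b-3p at 0.93 (SE 0.35), and miR-542-5p, miR-297a-5p and miR-297c-5p at means under 10 CPM. None of these passed, as the lowest adjusted p over all tested miRNAs was 0.815 in edgeR.

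**Figure D2:**
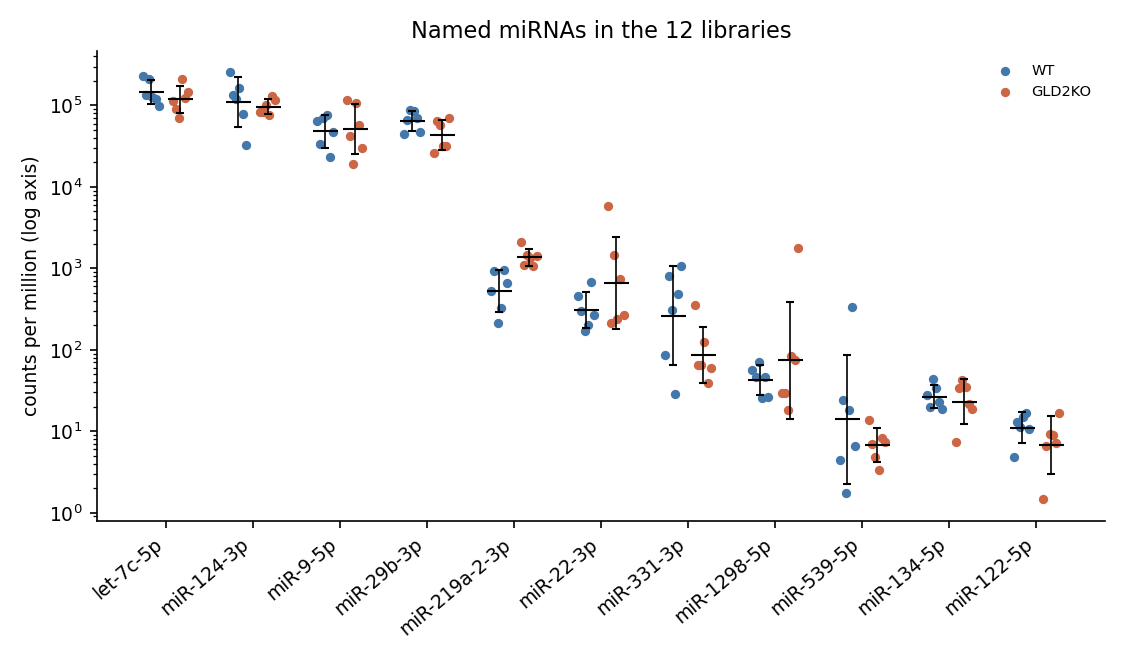
CPM of 11 named miRNAs in each library, on a log axis, with points for single libraries and bars for the geometric mean with 1 SD of log2 CPM (n = 6 per genotype). Single libraries stand far from their group for miR-1298-5p (1767 CPM in GLD2KO replicate 6) and miR-539-5p (334 CPM in WT replicate 5), while the 6 GLD2KO libraries of miR-219a-2-3p all lie above the 6 WT libraries.

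The common biological coefficient of variation between libraries of a genotype was 0.581 in edgeR, and the median half-width of the 95% confidence intervals was 0.955 on the log2 scale, a ratio of 1.94. The interval lay within a 2-fold change either way for 89 of the 521 miRNAs (17.1%) and within a 1.5-fold change for 0. For let-7c-5p it ran from -1.06 to 0.50, and for miR-125b-5p from -0.79 to 0.72. Among the 81 miRNAs with a mean of at least 1000 CPM, 20 had an interval within a 2-fold change and 1 had an unadjusted p under 0.05. The count of 89 was 39 without GLD2KO replicate 2, and between 43 and 56 without WT replicates 1, 2, 4 or 5 or GLD2KO replicates 5 or 6.

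Both miRNAs listed for Gld2, described in other cells as stabilised by it or losing 3′ adenylation without it, had intervals that included 0. The liver-enriched miR-122-5p (chromosome 18, 65248861 to 65248926), rare in these libraries, was at 11.9 CPM in WT and 8.43 CPM in GLD2KO, a log2 fold change of -0.49 (95% confidence interval -1.46 to 0.48). The dendritic miR-134-5p, from the Mirg transcript of the Dlk1-Dio3 locus (chromosome 12, 109734139 to 109734209), was at 27.9 and 26.7 CPM, a log2 fold change of -0.06 (interval -0.95 to 0.83). With miR-134-3p they formed a list of 3 tested members, all lower in GLD2KO with a median log2 fold change of -0.24, and the list did not pass limma's camera test (adjusted p = 0.572). None of the 3 passed when adjusted over the list alone or over all tested miRNAs.

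The let-7 family held 29.8 ± 5.58% of counts in WT and 27.5 ± 5.50% in GLD2KO (exact permutation, adjusted p = 0.904). Of its 22 tested members 8 were higher and 14 lower, with a median log2 fold change of -0.11 and 0 past the threshold (camera adjusted p = 0.522). Gld2 has been described as one of the terminal transferases that act on the precursors of group II let-7 miRNAs, which include let-7b, let-7d and let-7f, whereas let-7c and let-7e belong to group I. The mean log2 CPM of 13 group II members exceeded that of 5 group I members by 0.20 ± 0.485 in WT and 0.49 ± 0.235 in GLD2KO (SD, n = 6 each), a difference of 0.29 between genotypes (two-sided exact permutation p = 0.240 over 924 relabellings). Each member counted equally, from let-7c-1-3p at a mean of 6.53 CPM to let-7c-5p at 139774 CPM. The hairpins of let-7a belong to both groups, so let-7a was left out. The group I member let-7c-2-3p is uncertain, as its mean of 508.17 CPM nearly equals the 508.15 CPM of let-7a-1-3p. By share of counts group I was the larger, at 14.96% against 12.01% in WT and 13.01% against 12.04% in GLD2KO. As lists, group II had a median log2 fold change of -0.01 (camera adjusted p = 0.882) and group I of -0.26 (adjusted p = 0.472).

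The 5p and 3p arms of the hairpins had nearly equal median fold changes. The median was 0.12 over 240 miRNAs from the 5p arm and 0.12 over 258 from the 3p arm, and neither arm stood apart from the other miRNAs (camera adjusted p = 0.984 for both). Of 167 hairpins with counts from both arms, 0 had a different arm ratio in limma, with a lowest adjusted p of 0.922, and 2 had an unadjusted p under 0.05 where chance gives 8.35. These were miR-22 and miR-28a, named after their values were seen. The log2 ratio of 5p to 3p counts of miR-22 was 1.13 ± 1.28 in WT and -1.01 ± 2.32 in GLD2KO, a difference of -2.14 (95% confidence interval -4.07 to -0.21), and -1.35 without GLD2KO replicate 1. For miR-28a the difference was 1.62 (interval 0.16 to 3.09).

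No list of neuronal or glial miRNAs passed the test. Neuron-enriched miRNAs, such as miR-124-3p and miR-9-5p, took 22.6 ± 5.48% of counts in WT and 22.4 ± 3.48% in GLD2KO, and of 23 tested members 12 were higher and 11 lower (median log2 fold change 0.05, camera adjusted p = 0.876). The list of activity-regulated and synaptic miRNAs, led by miR-138-5p and miR-181a-5p, had 10 of 17 members higher and a median of 0.23 (adjusted p = 0.876). Of 4 oligodendrocyte miRNAs, miR-219a-2-3p passed when adjusted over the list alone (edgeR adjusted p = 0.0291), while 0 passed over all tested miRNAs. The others of that list lay lower, with miR-338-3p at -0.02, miR-219a-5p at -0.17 and miR-338-5p at -0.74, and the list did not pass (camera adjusted p = 0.876). The sign of miR-338-3p turned without WT replicate 3, to 0.47. In each of the other 16 lists 0 members passed when adjusted over the list alone.

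Microglia and blood miRNAs had a median log2 fold change of 0.34 (7 of 11 higher, camera adjusted p = 0.617), and vascular miRNAs of 0.17 (4 of 7 higher, adjusted p = 0.617). The mean of the vascular members was -0.15, opposite in sign to their median, and camera pointed down for them. The red blood cell miR-451a ranged from 615 to 22861 CPM among WT libraries alone. Medians were 0.26 for miRNAs of the Sfmbt2 introns (19 of 29 higher, adjusted p = 0.543; 15 of 21 higher, median 0.23 and adjusted p = 0.373 with members of the same counts taken once), 0.18 for the miR-30 family (6 of 11 higher, adjusted p = 0.617), 0.05 for the miR-29 family (4 of 7 higher, adjusted p = 0.472) and -0.13 for miRNAs of injury and hypoxia (3 of 8 higher, adjusted p = 0.472). For the miR-30 family camera pointed down, with a mean of 0.02. The mean of the miR-29 members was -0.14, opposite in sign to their median, and the camera test also pointed down. That median turned to -0.35 without GLD2KO replicate 1 and to -0.26 without GLD2KO replicate 5. The imprinted Dlk1-Dio3 locus on chromosome 12 had 51 of 82 members higher, with a median of 0.05, which lies under the median of all tested miRNAs (camera adjusted p = 0.882). Its share of counts was 5.73 ± 1.19% in WT and 7.68 ± 1.69% in GLD2KO (exact permutation, adjusted p = 0.258), and its miR-136-5p alone reached 88684 CPM in GLD2KO replicate 4.

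MiRNAs of the growth-promoting miR-17-92 cluster and its paralogous clusters were higher in GLD2KO for 12 of 13 members, with a median log2 fold change of 0.36, and did not pass (camera adjusted p = 0.142, and 0.618 with an estimated correlation). The list passed without GLD2KO replicate 1 (adjusted p = 0.0492, median 0.34) and with no low-count filter (adjusted p = 0.0274, median 0.37). Its median was 0.60 without WT replicate 1 (adjusted p = 0.0711). Its members miR-93-5p and miR-20a-5p had log2 fold changes of 0.99 (SE 0.47) and 1.08 (SE 0.51). The share of counts of this list was 0.0634 ± 0.0171% in WT and 0.108 ± 0.0282% in GLD2KO (exact permutation p = 0.00866, adjusted p = 0.0736 over the 17 lists). The adjusted p of that share was 0.0368 without GLD2KO replicate 6.

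The list of miRNAs of other brain regions and of epithelia was higher in GLD2KO, with 9 of 9 tested members above 0 and a median log2 fold change of 0.84 (camera adjusted p = 0.0288, with 0 members past the threshold). The call was lost with an estimated correlation (adjusted p = 0.618 with an estimated correlation) and was not made by fry (adjusted p = 0.401). It was also lost with the replicate number as a block, at a median of 0.42 (camera adjusted p = 0.139). Of the 9 members, 6 come from introns of Htr2c, a receptor gene that choroid plexus epithelium expresses strongly, and 3 belong to the epithelial miR-200 family. The median was 0.04 without GLD2KO replicate 6, the library with 1767 CPM of miR-1298-5p (camera adjusted p = 0.640). It stayed between 0.77 and 0.90 without WT replicates 1, 2 or 4 or GLD2KO replicate 4, which also ended the call, at adjusted p values of 0.0711, 0.0545, 0.149 and 0.0601. The share of counts of the list was 0.0198 ± 0.00527% in WT and 0.0630 ± 0.0719% in GLD2KO (exact permutation p = 0.00866, adjusted p = 0.0736), a difference of 0.0432 percentage points. That difference was 0.0140 (adjusted p = 0.0859) without GLD2KO replicate 6 and 0.0515 (adjusted p = 0.0368) without GLD2KO replicate 3. Among choroid plexus and cilia miRNAs 6 of 8 were higher, with a median of 0.60 (camera adjusted p = 0.882), and the median was -0.04 without GLD2KO replicate 6. In that list miR-204-5p, a choroid plexus miRNA from an intron of Trpm3, was at 3113 CPM in WT and 4973 CPM in GLD2KO, and miR-34c-5p, a miRNA of ciliated cells, at 555 and 1533 CPM. Without GLD2KO replicate 6 the GLD2KO means were 3296 CPM for miR-204-5p and 643 CPM for miR-34c-5p. Without that library the GLD2KO mean of miR-204-3p stayed above its WT mean, at 23.09 against 11.97 CPM. Those of miR-211-5p (9.12 against 25.81 CPM in WT) and miR-449a-5p (18.51 against 31.9 CPM) lay below. The others were miR-34b-5p at 314 against 370 CPM, miR-34b-3p at 37.41 against 36.01 CPM and miR-34c-3p at 48.22 against 52.84 CPM.

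**Figure D3:**
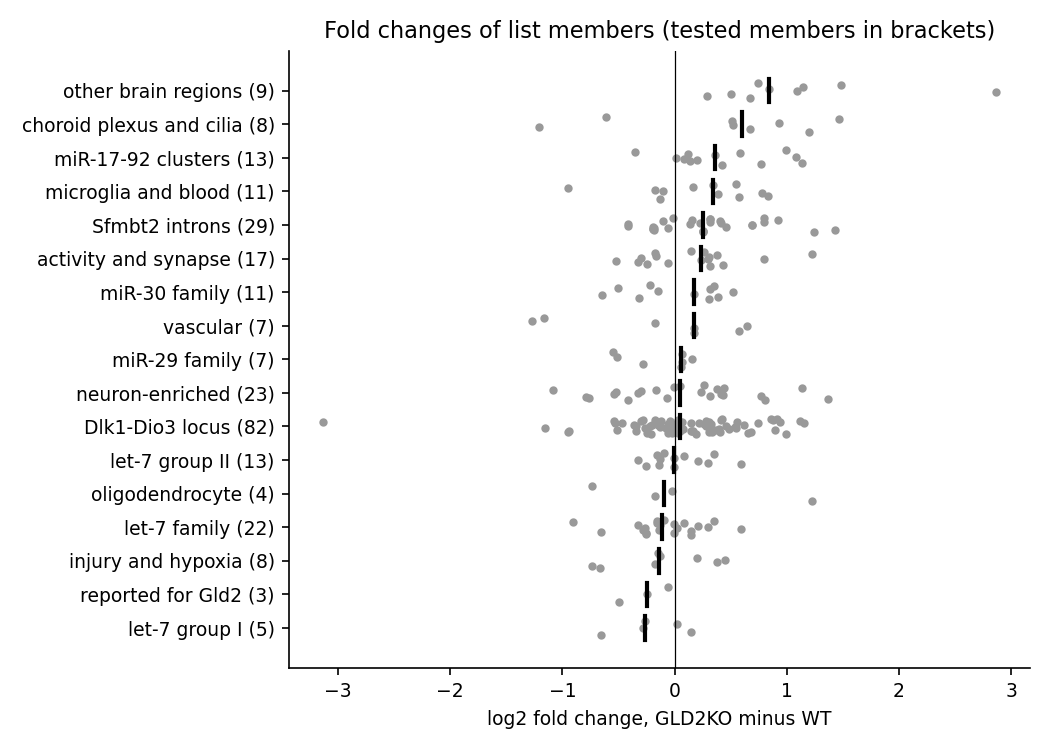
Log2 fold changes (GLD2KO minus WT) of the tested members of 17 miRNA lists, with a grey point for each member, a black bar at the median and the number of tested members in brackets. The list of other brain regions has its median at 0.84 and all 9 members above 0, and most other lists scatter on both sides of 0.

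**Figure D4:**
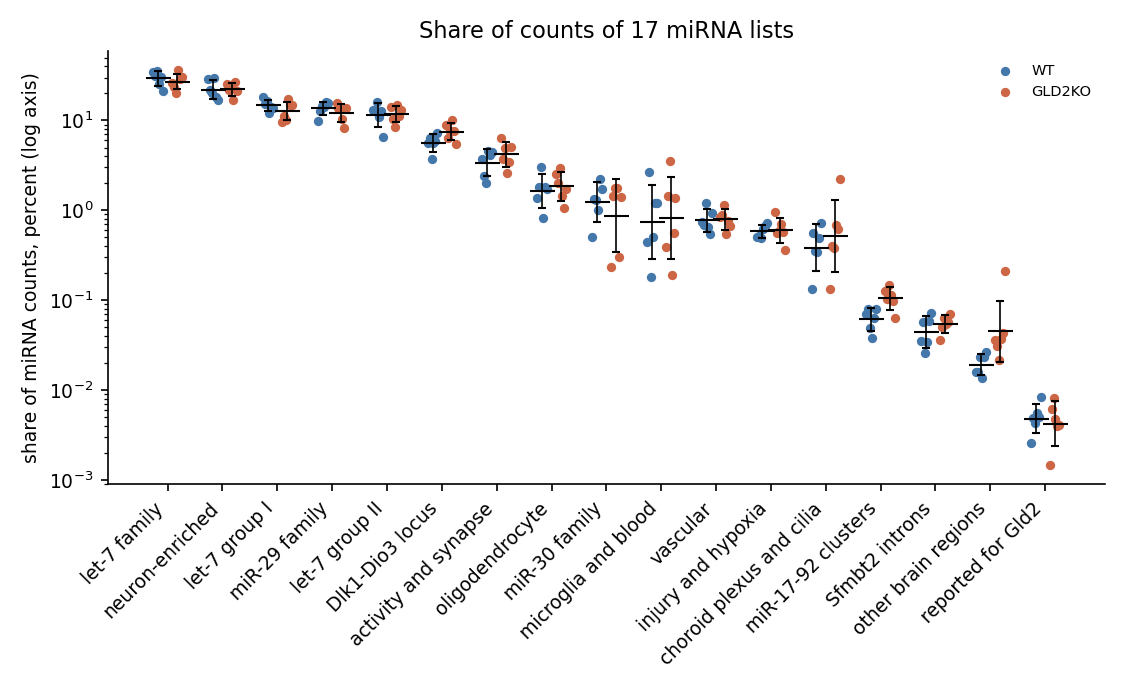
Share of miRNA counts of the 17 lists in each library, in percent on a log axis, with points for single libraries and bars for the geometric mean with 1 SD of the log2 share (n = 6 per genotype). The let-7 family has the largest mean share in both genotypes, and 1 GLD2KO library stands above the rest in the lists of other brain regions (0.209%) and of choroid plexus and cilia (2.20%).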

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

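The tests of choroid plexus tissue were chosen after the values were seen. Of 150 groups of 6 libraries checked, 8 had 1 library far from the other 5, where chance gives about 1 in 20, or 7.5. They fell in 4 libraries, 3 of them in GLD2KO replicate 6.

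In WT replicate 6, let-7a-5p stood at 6391 CPM against 25409 to 44728 CPM in the other WT libraries, and let-7j, named as a member of the same family, at 217 CPM against 1731 to 2874 CPM. In WT replicate 1, miR-30d-5p stood at 684 CPM against 2060 to 3193 CPM. In GLD2KO replicate 4, miR-136-5p stood at 88684 CPM against 11584 to 17327 CPM, and miR-204-3p at 5.69 CPM against 22.1 to 48.4 CPM.

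In GLD2KO replicate 6, miR-1298-5p stood at 1767 CPM against 18.1 to 83.0 CPM in the other GLD2KO libraries. The list of other brain regions took 0.209% of its counts (95% Wilson interval 0.203 to 0.215%) against 0.0215 to 0.0429%, and the choroid plexus and cilia list 2.20% (interval 2.18 to 2.22%) against 0.135 to 0.687%. A candidate explanation for the higher list of other brain regions is choroid plexus tissue in this 1 library. Of the 8 choroid plexus and cilia miRNAs 6, the arms of 3 hairpins, were highest of the 12 libraries there. Of the most abundant, miR-204-5p was at 13357 CPM against a median of 2912 CPM elsewhere, and miR-34c-5p at 5982 against 397 CPM. Not highest there were miR-211-5p, at 21.8 CPM against a median of 23.0 CPM elsewhere, and miR-449a-5p, at 32.3 CPM against 22.4 CPM. These ranks are no separate test, since the share of this list is among the values that flagged this library. Without this library the median log2 fold change of the list of other brain regions was 0.037, against 0.84 with it. That fall is no test, since the Htr2c members of the list marked this library. For the Htr2c members choroid plexus tissue stays open. For miR-200a-3p, miR-200b-3p and miR-429-3p the tables argue against it, since their mean log2 fold change was 1.15 without the library and 1.03 with it, and a genotype difference in them stays open at edgeR adjusted p values from 0.815 to 0.841.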

How the results depend on the processing

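The alternatives without 3 outlying libraries (GLD2KO replicates 1 and 4 and WT replicate 3) and with miRNAs of the same counts taken once were chosen after seeing the data; the others were planned. Over 2083 alternative values, 144 changed sign, in 36 results that include 19 of 52 named miRNAs, 9 list medians and 7 differences in share. Of these changes 0 involved a value past a threshold and 11 exceeded the error of the value. The count of 0 miRNAs became 7 with no low-count filter and stayed 0 under the other alternatives. Leaving out the filter raised the prior degrees of freedom from 8.89 to 704, with rare miRNAs in the estimate of the spread, and 85 of 1325 miRNAs then had an unadjusted p under 0.05. The count of 1 list became 2 with no low-count filter, 0 with an estimated correlation, 0 with the replicate block, and between 0 and 2 without each library in turn. The count of list shares past the threshold, 0, ranged from 0 to 1 without each library. The 89 intervals within a 2-fold change ranged from 39 to 96 without each library. The difference in library totals, -0.614 in units of 1000000 counts, ranged from -0.784 to -0.482. The arm ratios, the let-7 group difference and the arm medians kept their side of the threshold in every alternative run.

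Some values took the other sign. Under limma-voom with quality weights, log2 fold changes were -0.40 for miR-29c-3p, -0.084 for miR-136-5p and -0.27 for miR-21a-5p, and without the 3 outlying libraries the median of the miR-29 family was -0.32. Without each library in turn the ranges were -0.26 to 0.47 for miR-338-3p, -0.38 to 0.22 for miR-29c-3p, -0.086 to 0.78 for let-7d-5p (0.60 with all libraries), -0.57 to 0.22 for miR-376a-3p, -0.27 to 0.81 for miR-136-5p (0.65 with all libraries) and -0.35 to 0.16 for the miR-29 median. The cause was not tested for these or for the lists. Other scalings moved the median log2 fold change of all tested miRNAs between 0.08 and 0.16.

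No clear pairing of WT and GLD2KO libraries by their shared numbers was seen, though 6 pairs cannot exclude a modest one. Correlations of deviations between same-numbered libraries ran from -0.232 to 0.241, and 1 of 6 WT libraries correlated best with its own number. With the replicate block 0 miRNAs were called, 48 intervals lay within a 2-fold change, and 0 lists passed, the list of other brain regions at a median of 0.42 and an adjusted p of 0.139. How far depth and other differences between libraries each limit the precision was not separated.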

Other observations

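The tests of cell makeup, of the shared miR-22 hairpin and of the count of genotype differences were chosen after their values were seen, as was the test of shared reads by sequence, which replaced a planned one by miRNA number because 18 of its 40 pairs differ by 3 or fewer edits. Correlations of 4 marker pairs of 2 cell types went both ways (-0.353 to 0.461) and decide nothing. For 3 of 521 miRNAs the 6 libraries of one genotype all lay on one side of the other 6, where chance gives 1.13. These were the oligodendrocyte miR-219a-2-3p (1062 to 2083 CPM in GLD2KO, at most 967 CPM in WT), the muscle-enriched miR-133b-3p (13.3 ± 3.21 CPM in WT and 25.4 ± 6.31 CPM in GLD2KO) and miR-153-5p, the rarer arm of a neuronal hairpin in an intron of Ptprn2 (6.45 ± 2.83 and 3.00 ± 1.02 CPM). None passed the adjusted threshold, and the 3 were picked after their values were seen.

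Random splits of the 12 libraries into groups of 6 gave counts as large as the genotypes did, so chance could not be excluded for the miRNAs with an unadjusted p under 0.05 or for the lists. Of 100 splits, the real one included, 66 gave at least the real 25 such miRNAs. All splits other than the real one gave 13 to 71, with a median of 27. At least the real 1 list was called in 59, with up to 5. For the miRNAs past the adjusted threshold and the hairpins with a different arm ratio the real count was 0, which all 100 splits reach by construction, so those splits decide nothing; the highest other counts were 2 and 1.

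Libraries of one genotype differed widely in single miRNAs, and these deviations followed the sequence of the miRNA more than its gene. Over the 430 miRNAs with a mean of at least 10 CPM, deviations from the genotype mean were correlated across the 12 libraries. The median r was 0.721 (95% bootstrap interval 0.398 to 0.800) in 102 pairs that share a seed but lie at least 1 Mb apart. The bootstrap drew families, groups of neighbours or hairpins and kept the 12 libraries fixed, so its intervals leave out variation between mice. The median was 0.04 (-0.02 to 0.08) in 296 pairs of different families within 10 kb, a difference of 0.682 (0.349 to 0.788). Without let-7 the seed family median was 0.574 (0.393 to 0.776) in 62 pairs. It was 0.403 (0.339 to 0.745) in the 32 of these with different miRNA numbers. Without chromosome 12, 44 neighbour pairs remained, with a median of 0.03 (-0.03 to 0.15). Capture or counting that depends on sequence could give such a difference. For the 2 arms of 121 hairpin names the median was 0.0920 (-0.03 to 0.15). Arms of 1 hairpin come from the same transcript and cells, but some names, such as miR-124, stand for several hairpins. The median pair thus showed no strong common deviation from differences in primary transcripts or cell makeup. Noise in the rarer arm, or variation that differs between arms, could hide the part of either, so neither is excluded. Of these pairs 56.2% correlated above 0, among them the arms of miR-1298 (0.73) and miR-34c (0.65). Of the 102 seed family pairs 75 differ by 3 or fewer edits per 20 bases of their hairpin arms. For these, shared reads stay open. Reads shared directly at up to 3 edits would not account for the other 27 pairs, in 6 families, whose median was 0.470 (0.331 to 0.738). However, both members of such a pair can share reads with another member of the family. For example, let-7k and miR-98-5p differ by 5 edits, but each differs from let-7b-5p by 2. Shared reads therefore stay open for some of the 27 pairs as well. Sequence-dependent capture and joint regulation of seed families, which was not tested, also stay open.

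The arms of miR-22 lay apart between genotypes, with a difference in log2 arm ratio of -2.14. A change in the shared hairpin would move both arms alike, but miR-22 was picked as the lowest p of 167 hairpins and its adjusted p was 0.922, so that explanation stays undecided. The unadjusted limma p ran from 0.0105 to 0.0907 without each library in turn, highest without GLD2KO replicate 1. The difference was -1.35 without GLD2KO replicate 1 and between -1.75 and -2.61 without each other library, and the p was over 0.05 without 6 of the 12, 5 of which moved the difference less. The p values therefore do not decide whether 1 far knockout library is the source, and that stays open.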
